A study of Homo sapiens with 9 samples.

How the data were processed

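The deposited data were 9 scanner files, 1 per array, and a table of processed values for all arrays. Per the file headers, the intensity values came from single-colour (Cy3) 4x44K whole human genome arrays, extracted with Agilent Feature Extraction 10.5.1.1, whose processed signal is corrected for spatial background and detrended but not normalized between arrays. The log2 values in the authors' table were deposited as processed, for 27014 probes, with column medians from 9.01 to 9.03, and the table does not state its background correction, normalization or probe filter. Each of its columns correlated more closely with the scanner values of its own array (r from 0.982 to 0.992 across probes) than with those of any other array (at most 0.985). The comparisons rest on the scanner files, and the table served as an alternative.

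The processed signal was taken as log2, and replicate spots of a probe were averaged. Spots that the software marked as outliers (150 to 257 per array) were left out. Each array was scaled by subtracting its 75th percentile. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which left 27583 of 41000 probes. The probe with the highest mean signal stood for its gene, giving 20088 genes, of which 13943 have a current symbol. Probes took their names from a RefSeq gene table: 25398 by transcript accession, 2510 by current symbol and 789 by a unique synonym, while 12303 kept the name in the file. Probe coordinates are hg18, per the file headers, and no genome sequence was at hand to remap them. The files do not state the exon that a probe lies in.

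Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with the package data.table (1.17.8), over all 9 arrays with group means only. P-values were adjusted over all genes by the method of Benjamini and Hochberg, and a gene passed at an adjusted p under 0.05. "Rose" and "fell" refer to genes past this test. An F test covered the 3 groups together. Metallothionein and spike-in means were compared by exact permutation tests. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Where a probe was well above background on no array of a group, its fold change is given as a lower bound. For this bound each array of that group was set to the lowest signal that counted as well above background on that array, or to its own value where this was higher, and the text says "at least N-fold".

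The 41 gene lists were tested with limma's camera at a preset correlation of 0.01, again with a correlation estimated for each list, and with fry. All of them had at least 5 measured members. The p-values of a list test were adjusted over the 41 lists. Counts of members past the test are given over all genes and, where it differs, adjusted over the list alone.

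The genes named were chosen by a rule. For each dose against control it took the 10 genes with the largest positive and the 10 with the most negative log2 fold change, and for 10 µM against 2 µM 5 of each. These had to pass the test, have values that did not overlap between the groups, and have a probe well above background on all 3 arrays of the brighter group. From each list it took up to 4 members with the largest absolute change among those past the test, or up to 2 where none passed, and from the metallothioneins every measured member. Names without a gene symbol were passed over, and some genes that the rule names are not reported here. The gene lists, this rule, the tests and most of the alternatives were fixed before the data were examined.

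The alternatives fixed with them were normexp background correction (offset 50), quantile normalization, median scaling, the authors' table, no filter on dim probes, only probes well above background on all 9 arrays, the mean of a gene's probes, every probe, trend and robust moderation, array weights, only the 2 groups compared, replicate number, slide or scan date as a block, a change of at least 2-fold, an adjusted p under 0.01 and leaving out each array in turn. Another 3 were added after the data were seen: arrays of the first scan date only, spots marked as outliers kept, and scaling to the spike-ins.

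Whether equal replicate numbers pair the samples was checked once on residuals from the group means. All 9 pairs of arrays with equal numbers correlated positively (r from 0.27 to 0.75 across genes) and pairs with unequal numbers at -0.49 to 0.13. Most pairs with equal numbers also shared a slide. Replicate 1 at 10 µM did not, and it correlated with replicate 1 of control and 2 µM at 0.35 and 0.45. With their replicate 2, on its own slide, it correlated at -0.01 and -0.03. The numbers were therefore taken as pairs, and values with the replicate block are given beside the comparisons where they change a call or move a count. Between control and 2 µM, equal numbers always shared a slide, so pairing and slide cannot be told apart there.

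In a self-test on simulated arrays with the observed spread of 19857 genes, 200 genes were changed in each of 5 runs in the 10 µM group. The test recovered 1.2% of changes of 0.5 (log2), 25.2% of changes of 1, 88.8% of changes of 2 and 97.2% of changes of 3, with 5.6 false calls per run. A shifted list was found in 5 of 5 runs and no other list was called. The simulated genes were independent of each other. These runs therefore could not show how often the preset correlation calls a list of correlated genes falsely. Of 5551 genes with several probes, 733 were called at 10 µM. Among the 5551, 1 gene had a probe that passed upward and another that passed downward. Probes that pointed the other way without passing were not counted.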

Results

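Gene expression was profiled in HepG2, a human hepatoma cell line that keeps many functions of hepatocytes, after 24 h in medium with cadmium chloride or in plain medium. There were 3 groups of 3 arrays: control, 2 µM cadmium (Cd) and 10 µM Cd. Each array held 45015 spots, of which 43376 were not controls and covered 41000 probes. Between 65.8% and 73.8% of these spots were well above background on an array, and no spot was saturated. The signal at the 75th percentile lay between 486 and 1451 intensity units. With 3 arrays per group, the number of arrays limits the precision of every value below. The p-values rest on replicates that the labels call independent.

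The arrays separated first by the higher dose. The leading principal component, with 49.0% of the variance, set the 3 arrays at 10 µM apart from the other 6. The next component, with 22.5%, set replicate 3 of every group apart from replicates 1 and 2. The replicate 3 arrays lay on 1 slide scanned on the later of 2 dates. Of the other slides, one held replicate 1 of the control and 2 µM groups, and the other held their replicate 2 with replicates 1 and 2 at 10 µM. Changes are given below as log2 fold change ± SE from limma with 3 arrays per group, relative to each array's 75th percentile. Scaling to spike-in RNA instead, a choice made after the data were seen, moved the median of all genes at 10 µM from 0.03 to -0.66. Smaller rises at 10 µM therefore depend on the scaling. The largest part of this move came from 10 µM replicate 3. Its spike-ins lay 2.86 (log2) above the 75th percentile, beside 1.49 and 1.58 in replicates 1 and 2. List medians with spike-in scaling, given below, carry the same shift for every list of a comparison and are not separate checks.

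**Figure D1:**
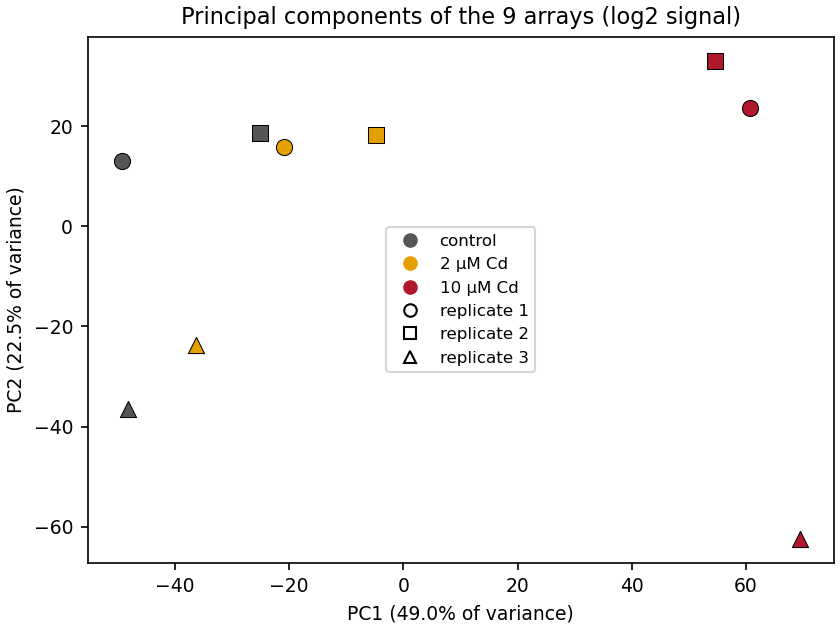
Principal components of the 9 arrays from normalized log2 signals, with PC1 (49.0% of the variance) on the x axis and PC2 (22.5%) on the y axis; colour gives the dose and marker shape the replicate. The 10 µM arrays lie apart on PC1, and replicate 3 of each group lies apart on PC2.

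Metallothioneins, the small cysteine-rich proteins that bind cadmium and zinc, were the known response by which the dose labels could be checked. Averaged over 12 measured metallothionein genes, the normalized log2 signal was 2.78 ± 0.89 (SD, n = 3) in control, 6.13 ± 0.27 (SD, n = 3) at 2 µM and 6.42 ± 0.58 (SD, n = 3) at 10 µM. The signal was 10.2-fold above control at 2 µM and 12.5-fold above it at 10 µM. Every treated array lay above every control array, with an exact two-sided permutation p of 0.1 at either dose, the smallest that 3 against 3 allows. The step between the doses was 0.29 (1.22-fold) with an exact permutation p of 0.6 between unpaired groups. By replicate pair it was 0.05, 0.15 and 0.67, higher at 10 µM in all 3 pairs, with an exact two-sided paired permutation p of 0.25, the smallest that 3 pairs allow; this paired test was chosen after the values were seen. With spike-in scaling the step was -0.33. Replicate 3 had the highest signal in each group, and in control it was 3.80 beside 2.38 and 2.16. Sequences of these paralogs are close, so a probe may also bind transcripts of its relatives.

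**Figure D2:**
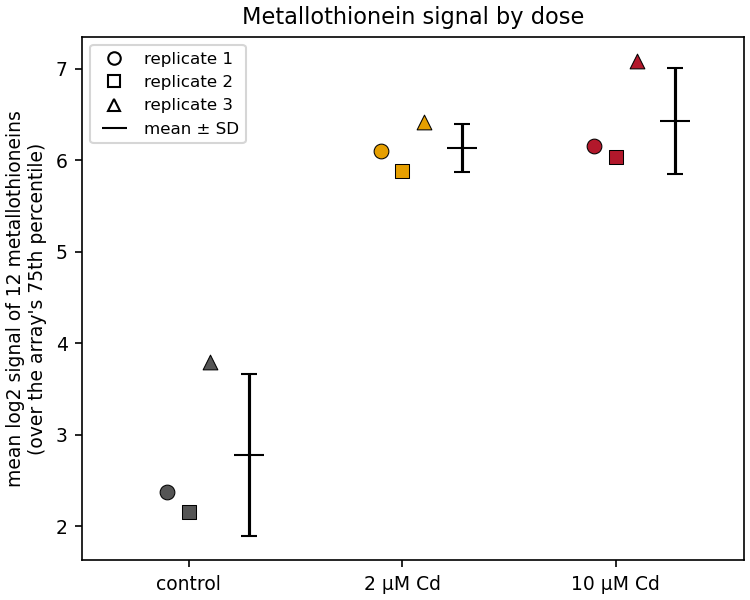
Mean normalized log2 signal of 12 metallothionein genes on each array (y axis) by dose (x axis), with marker shape for the replicate and bars for the mean ± SD of 3 arrays. All 6 treated arrays lie above the 3 control arrays, whose mean was 2.78, and the means at 2 µM and 10 µM were 6.13 and 6.42, a step that turned to -0.33 with spike-in scaling.

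The first comparison asked what the lower dose changed. At 2 µM, 17 of 20088 genes rose and 0 fell, and most of those with a symbol were metallothioneins. The strongest rise was that of MT1JP, a metallothionein pseudogene, at 8.38 ± 0.67 (adjusted p = 0.00209). MT1E rose by 3.57 ± 0.50, MT1F by 3.45 ± 0.43, MT1B by 3.38 ± 0.44, MT1G by 3.35 ± 0.45, MT1H by 3.27 ± 0.45, MT1X by 3.26 ± 0.44 and MT1L by 3.20 ± 0.44. HSPA6, a stress-inducible HSP70 chaperone, rose by 3.06 ± 0.40 and CCL26, a chemokine that attracts eosinophils, by 3.70 ± 0.49, both with an adjusted p of 0.0491.

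TUSC3, a subunit of the oligosaccharyltransferase complex, and LDHB, the lactate dehydrogenase subunit of heart and many other tissues, were not well above background on any control array and were so on all 3 arrays at 2 µM. TUSC3 was at least 7.87-fold higher than in control and LDHB at least 3.09-fold, each with an adjusted p of 0.00209. The other called genes, named after their values were seen, were UCHL1, a neuronal ubiquitin hydrolase (2.96 ± 0.35), CT45A1, a cancer testis antigen, at least 1.28-fold higher, and AK025975 (3.10 ± 0.25), BG188151 (at least 1.72-fold higher) and LOC100129788 (at least 1.71-fold higher), which have no gene symbol. CT45A1, BG188151 and LOC100129788 were well above background on no control array. The probes lie on chromosome 16 at 55227173 to 55227232 for MT1JP and 55258247 to 55258306 for MT1G, on chromosome 8 at 15645432 to 15645491 for TUSC3, on chromosome 12 at 21679716 to 21679775 for LDHB and on chromosome 1 at 159762782 to 159762841 for HSPA6 (hg18).

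Of the 12 metallothioneins, 8 rose at 2 µM and 4 did not pass, and 11 rose when adjusted over the list alone. Those that did not pass were MT1M at 3.49 ± 0.53, MT1A at 2.93 ± 0.44, MT2A at 2.05 ± 0.42 and MT3, the brain form, at -0.06 ± 0.20. The list's median change was 3.31 (camera adjusted p = 2.15e-47). The medians within slides 1, 2 and 3 were 3.67, 3.60 and 2.56. With the replicate number as a block, MT1A (adjusted p = 0.00207), MT1M (adjusted p = 0.00946) and MT2A (adjusted p = 0.0222) passed as well.

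Immediate early genes, which code for transcription factors and phosphatases made within minutes of a stimulus, shifted up at 2 µM as a list. None of the 39 passed on its own and 12 did when adjusted over the list alone. The median was 0.45 (camera adjusted p = 1.21e-20), and 0.57, 0.44 and 0.49 within slides 1, 2 and 3. The members with the highest values were GADD45G at 2.02 ± 0.57 and FOS at 1.85 ± 0.43. Coagulation and complement factors, secreted by hepatocytes, shifted down, with a median of -0.37 (camera adjusted p = 5.87e-13) and -0.42, -0.33 and -0.35 within the slides. Of these 35 genes none passed, and 2 did when adjusted over the list alone. KNG1, the kininogen gene, stood at -1.20 ± 0.27 and F13B at -1.12 ± 0.26. The cytochromes P450, which oxidise drugs and steroids, had a median of -0.21 (camera adjusted p = 2.13e-05), and -0.18, -0.23 and -0.28 within the slides, with CYP3A7 at -1.26 ± 0.34 and CYP4F3 at -0.95 ± 0.18. None of the 26 P450 genes passed, and 1 did when adjusted over the list alone. These 3 lists and the metallothioneins were the 4 lists whose shift also held with an estimated correlation.

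Another 13 lists shifted at 2 µM with camera's preset correlation alone. The hepatocyte secreted proteins had a median of -0.38 (adjusted p = 0.133 with an estimated correlation) and cholesterol synthesis a median of -0.46 (adjusted p = 0.22 with an estimated correlation). No member of either passed; GC, the vitamin D binding protein, stood at -1.38 ± 0.54, IGFBP1 at 1.32 ± 0.36 and MVK, the mevalonate kinase, at -0.59 ± 0.20. Actin cytoskeleton and extracellular matrix genes had a median of 0.23 (adjusted p = 0.133 with an estimated correlation), ribosome biogenesis genes 0.14 (adjusted p = 0.22 with an estimated correlation) and NRF2 targets 0.08 (adjusted p = 0.133 with an estimated correlation), with no member past the test. With spike-in scaling the medians were 0.163 for the actin and matrix genes, 0.067 for ribosome biogenesis and 0.014 for the NRF2 targets. AKR1C1, an aldo-keto reductase, stood at 0.76 ± 0.27 among the NRF2 targets and MMP1, a collagenase, at 1.53 ± 0.61 among the matrix genes. The medians were -0.20 for fatty acid and triglyceride synthesis, -0.16 for fatty acid oxidation, -0.16 for bile acid synthesis and transport, -0.18 for amino acid and urea metabolism (1 gene lower adjusted over the list alone) and -0.19 for ribosomal proteins. They were 0.12 for aminoacyl tRNA synthetases, 0.08 for autophagy and lysosome genes and 0.04 for heat shock chaperones, of which HSPA6 alone passed (2 genes adjusted over the list alone). With an estimated correlation the adjusted p of these 8 lists was 0.345, 0.22, 0.293, 0.39, 0.827, 0.541, 0.387 and 0.243. With spike-in scaling the medians were -0.03 for heat shock chaperones, 0.007 for autophagy and lysosome genes and 0.051 for aminoacyl tRNA synthetases. Medians below 0 fell further. The call of the heat shock chaperones ended with the replicate block (camera adjusted p = 0.0562, range over all alternatives 0.00132 to 0.367). Without control replicate 3 these 8 lists and the NRF2 targets all lost their call (adjusted p from 0.0511 to 0.384). Some did so without 2 µM replicate 1 (5 lists, 0.069 to 0.262), 2 (4 lists, 0.0669 to 0.152) or 3 (3 lists, 0.0675 to 0.0822), without control replicate 1 (autophagy genes, 0.103) or 2 (aminoacyl tRNA synthetases, 0.0665, and heat shock chaperones, 0.269), or without 10 µM replicate 2 or 3 (heat shock chaperones, 0.0585 and 0.0976).

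These calls at 2 µM rested on few arrays. Without control replicate 1, control replicate 2, 2 µM replicate 1, 2 or 3, or 10 µM replicate 1 or 2, limma called 4, 5, 4, 4, 10, 6 and 7 genes up; MT1JP, TUSC3, LDHB and AK025975 kept their call in each of the 9 fits that left out 1 array. With normexp background correction the changes shrank to 0.66 for LDHB, 1.099 for TUSC3, 1.34 for CCL26 and 1.47 for HSPA6 and these calls ended, and with the authors' deposited table those of LDHB (0.85), CCL26 (1.58) and HSPA6 (1.67) did, so the bounds given for LDHB and TUSC3 hold for the processed signal only. In limma 625 of 20088 genes, of either direction, had an unadjusted p under 0.05, fewer than the share of 0.05 that unchanged genes would give. The fit has no replicate block, so differences between replicate numbers add to its spread. Few calls here therefore do not show that few genes changed. In place of the 17 genes higher and 0 lower, the slide block gave 24 up and 2 down (16 of the 17 shared) and the replicate block 25 up and 3 down (16 shared).

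**Figure D3:**
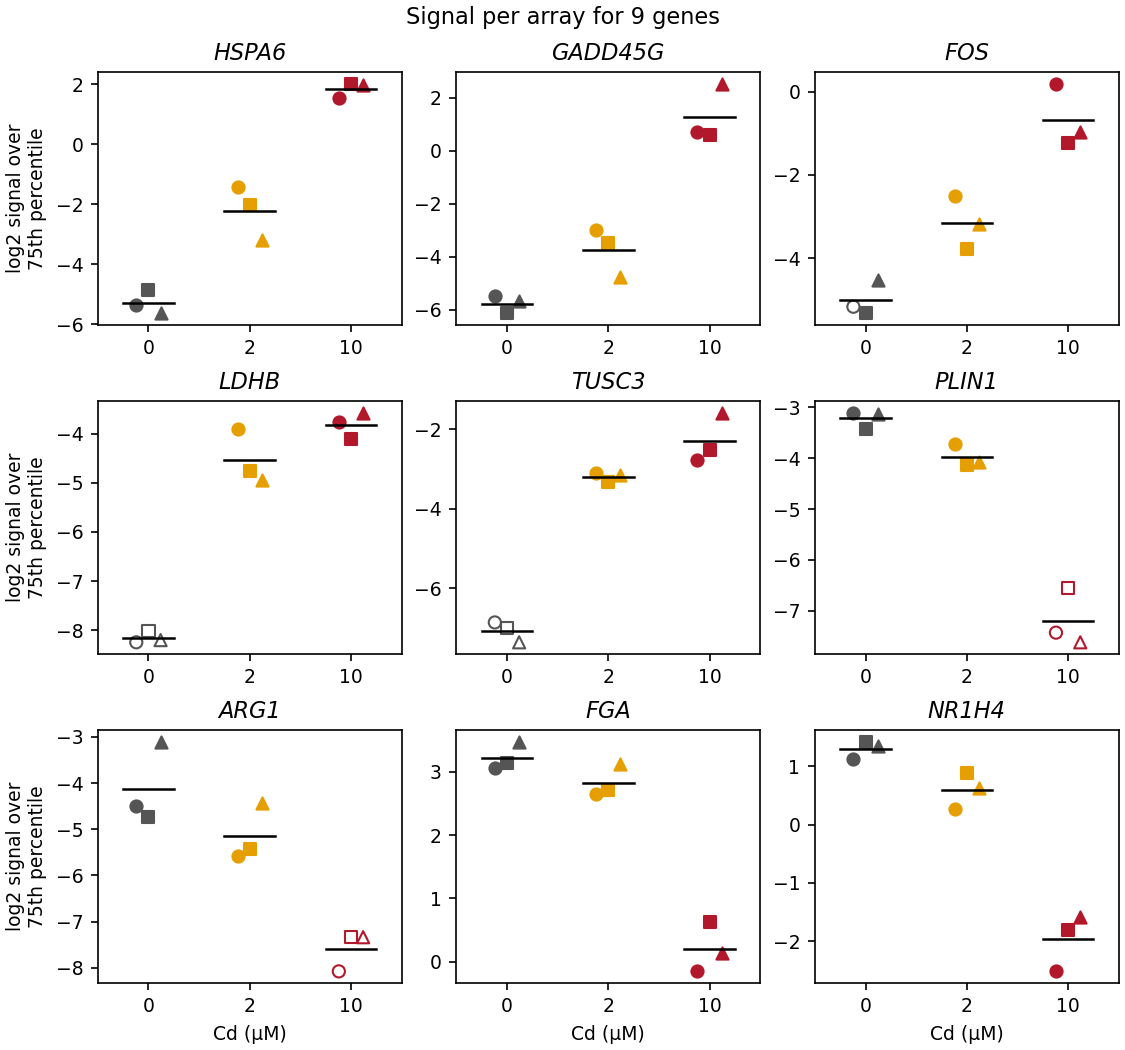
Normalized log2 signal (y axis, over the array's 75th percentile) on each of 9 arrays for 9 genes by dose in µM (x axis), with lines for group means, open markers for arrays where the probe was not well above background, and marker shape for the replicate. HSPA6 stepped from -5.28 in control to -2.22 and 1.84, while TUSC3 and LDHB were open on all 3 control arrays and filled at both doses.

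The second comparison asked what the higher dose changed. At 10 µM, 1612 genes rose and 1172 fell, of which 1161 rose and 620 fell by at least 2-fold. Among the gene lists, 11 of 12 metallothioneins and 30 of 39 immediate early genes rose, while 25 of 35 coagulation and complement genes and 26 of 41 hepatocyte secreted proteins fell. HSPA6 rose by 7.12 ± 0.40, or 140-fold (adjusted p = 6.67e-05), from a normalized log2 signal of -5.28 ± 0.39 (SD, n = 3) in control to 1.84 ± 0.27 (SD, n = 3). GADD45G, a stress-induced growth arrest gene, rose by 7.04 ± 0.57, or 131-fold (adjusted p = 0.000203). FGA, the fibrinogen alpha chain, fell by 3.02 ± 0.24 (adjusted p = 0.000203), from 3.23 ± 0.22 (SD, n = 3) to 0.21 ± 0.40 (SD, n = 3).

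The other genes with the largest rises were MT1JP at 8.69 ± 0.67, CCL26 at 6.12 ± 0.49 and HTRA3, a serine protease, at 5.39 ± 0.35. Probes of 5 more were not well above background on any control array. These were MLC1, an astrocyte membrane protein, at least 43.5-fold higher, ARC, an activity-regulated neuronal gene, at least 41.0-fold, NPPC, the C-type natriuretic peptide, at least 25.6-fold, SPANXA1, a sperm protein, at least 11.6-fold, and DEFB103B, a beta defensin, at least 7.63-fold. Among the largest falls were ALDH8A1, an aldehyde dehydrogenase of tryptophan breakdown (-3.81 ± 0.26), ZG16 (-3.65 ± 0.43), the peptidoglycan amidase PGLYRP2 (-3.48 ± 0.39), the melanocortin receptor accessory protein MRAP (-3.27 ± 0.18), the betaine transporter SLC6A12 (-3.27 ± 0.43), C8B of the complement membrane attack complex (-3.27 ± 0.32) and the bile acid receptor gene NR1H4 (-3.26 ± 0.26). PLIN1, a lipid droplet coat protein, was at least 7.93-fold lower, ARG1, the urea cycle arginase, at least 4.50-fold and NOL4 at least 4.33-fold, with no array at 10 µM well above background. The adjusted p of these 20 genes, HSPA6 and GADD45G included, lay between 6.67e-05 and 0.00133. The probes lie on chromosome 9 at 91410709 to 91410768 for GADD45G, on chromosome 4 at 155726698 to 155726757 for FGA, on chromosome 15 at 88009232 to 88009291 for PLIN1, on chromosome 6 at 131947066 to 131947125 for ARG1 and on chromosome 12 at 99481322 to 99481381 for NR1H4 (hg18).

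Of 12 metallothioneins, 11 rose at 10 µM, also when adjusted over the list alone. MT1E rose by 3.95 ± 0.50, MT1M by 3.90 ± 0.53, MT1G by 3.69 ± 0.45 and MT2A by 2.48 ± 0.42, while MT3 stood at -0.25 ± 0.20. The list's median was 3.66, and 3.85 and 3.35 within slides 2 and 3 (camera adjusted p = 4.14e-11, but adjusted p = 0.18 with an estimated correlation), and 2.98 with spike-in scaling. Of 39 immediate early genes 30 rose, none fell and 9 did not pass, and 32 rose when adjusted over the list alone. FOS rose by 4.33 ± 0.43, GADD45B by 3.91 ± 0.26 and the phosphatase DUSP5 by 3.53 ± 0.23. Their median was 1.68 (camera adjusted p = 2.56e-20), and 1.71 and 1.54 within slides 2 and 3, and the shift also held with an estimated correlation (adjusted p = 0.0158). With spike-in scaling the median was 1.00.

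Among 32 cytosolic heat shock chaperones 6 rose, none fell and 26 did not pass, and 11 rose when adjusted over the list alone. CRYAB, a small heat shock protein, rose by 3.92 ± 0.60 and HSPA1A, the major inducible HSP70, by 2.73 ± 0.30. Their median was 0.23 (camera adjusted p = 0.00818, adjusted p = 0.12 with an estimated correlation) and turned to -0.46 with spike-in scaling. Of 47 actin cytoskeleton and extracellular matrix genes 19 rose and 28 did not pass (24 rose adjusted over the list alone). LAMB3, a laminin chain, rose by 3.82 ± 0.63, and the matrix metalloproteinases MMP3 by 3.65 ± 0.27 and MMP1 by 3.41 ± 0.61. The median was 0.79, and 0.79 and 0.57 within slides 2 and 3 (camera adjusted p = 4.03e-10, adjusted p = 0.0805 with an estimated correlation), but 0.10 with spike-in scaling. Of 43 autophagy and lysosome genes 6 rose, 1 fell and 36 did not pass; GABARAPL1 rose by 1.27 ± 0.19, OPTN by 1.03 ± 0.20 and SQSTM1, an autophagy receptor, by 0.79 ± 0.16. The median was 0.28 (camera adjusted p = 0.00586, adjusted p = 0.293 with an estimated correlation) and -0.41 with spike-in scaling. Of 39 apoptosis regulators 8 rose and 2 fell (12 and 2 adjusted over the list alone), with PMAIP1, a BH3-only protein, at 2.06 ± 0.32, BIK at 1.85 ± 0.30 and the death ligand TNFSF10 at -1.67 ± 0.31. Their median of 0.21 (adjusted p = 0.366 with an estimated correlation) was -0.48 with spike-in scaling.

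Several stress pathways had members on both sides and no shift as a list by camera, although fry called the NRF2 targets and the acute phase genes (adjusted p = 0.00225 each, ranges over all alternatives 0.00225 to 0.274 and 0.00225 to 0.539). Among 35 NRF2 targets 6 rose, 2 fell and 27 did not pass (8 rose and 3 fell adjusted over the list alone); ME1 rose by 1.63 ± 0.27, the cystine transporter SLC7A11 by 1.46 ± 0.23 and GCLM, of glutathione synthesis, by 1.35 ± 0.22. Among 34 genes of ATF4 and the integrated stress response 6 rose and 3 fell (7 and 3 adjusted over the list alone), with PPP1R15A (GADD34) at 2.80 ± 0.24, ATF3 at 1.62 ± 0.19 and GDF15 at 1.59 ± 0.28. Of 30 endoplasmic reticulum chaperones and folding factors 2 rose and 2 fell, EDEM1 by 1.37 ± 0.19 and XBP1 by -0.96 ± 0.17 among them. Of 30 p53 targets 6 rose and 1 fell (9 and 2 adjusted over the list alone), with PMAIP1 again and PLK3 (1.61 ± 0.31) and PLK2 (1.51 ± 0.20) among the risers. Of 23 acute phase and inflammation genes 6 rose and 2 fell; CXCL8, the chemokine interleukin 8, rose by 2.58 ± 0.48, BIRC3 by 2.23 ± 0.19 and LIF by 2.20 ± 0.18. Hypoxia response genes numbered 26, of which 6 rose and 1 fell; NDRG1 rose by 1.78 ± 0.28 and CA12 was at least 2.57-fold higher, while EPO, the erythropoietin gene, fell by 2.57 ± 0.18. Of 28 zinc and metal transporters 2 rose and 4 fell (5 and 7 adjusted over the list alone), among the latter SLC30A10 (-2.97 ± 0.25), a manganese exporter, SLC39A5 (-1.53 ± 0.16) and ATP7B (-0.95 ± 0.19), the copper exporter of Wilson disease. Of 28 glycolytic genes 5 rose and 2 fell (5 and 5 adjusted over the list alone). LDHB was at least 5.11-fold higher, HK1 rose by 2.56 ± 0.25 and PFKP by 2.10 ± 0.32, and PKLR, the liver pyruvate kinase, fell by 1.76 ± 0.26; the median of this list was -0.07 and its mean 0.17.

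Lists of coagulation and complement genes, hepatocyte secreted proteins and liver transcription factors had more members that fell than rose at 10 µM. Of 35 coagulation and complement genes 25 fell, none rose and 10 did not pass (28 fell adjusted over the list alone). FGG fell by 2.81 ± 0.46 and C8A by 2.72 ± 0.40. The median was -1.37, and -1.47 within both slides 2 and 3 (camera adjusted p = 1.52e-22), and the shift also held with an estimated correlation (adjusted p = 0.00959). With spike-in scaling the median was -2.06. Of 41 hepatocyte secreted proteins 26 fell, 3 rose and 12 did not pass, and 31 fell when adjusted over the list alone. Haptoglobin (HP) fell by 2.94 ± 0.46, ITIH1 by 2.87 ± 0.31 and the cortisol carrier SERPINA6 by 2.70 ± 0.22, while IGFBP1, an insulin-like growth factor binding protein, rose by 2.91 ± 0.36. The median was -1.25, and -1.30 and -1.20 within slides 2 and 3 (camera adjusted p = 1.99e-15, adjusted p = 0.0805 with an estimated correlation), and -1.94 with spike-in scaling. Of 29 liver transcription factors 8 fell, 2 rose and 19 did not pass (11 fell and 2 rose adjusted over the list alone), with CEBPA at -1.94 ± 0.20 and HNF4A at -1.51 ± 0.30 (median -0.41, adjusted p = 0.165 with an estimated correlation, and -1.095 with spike-in scaling). At the same dose 6 of 9 measured markers of other cell lines that were dim in the controls rose (median 1.82), and of 6 measured endothelial markers (12 listed) 4 rose (median 2.23).

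**Figure D4:**
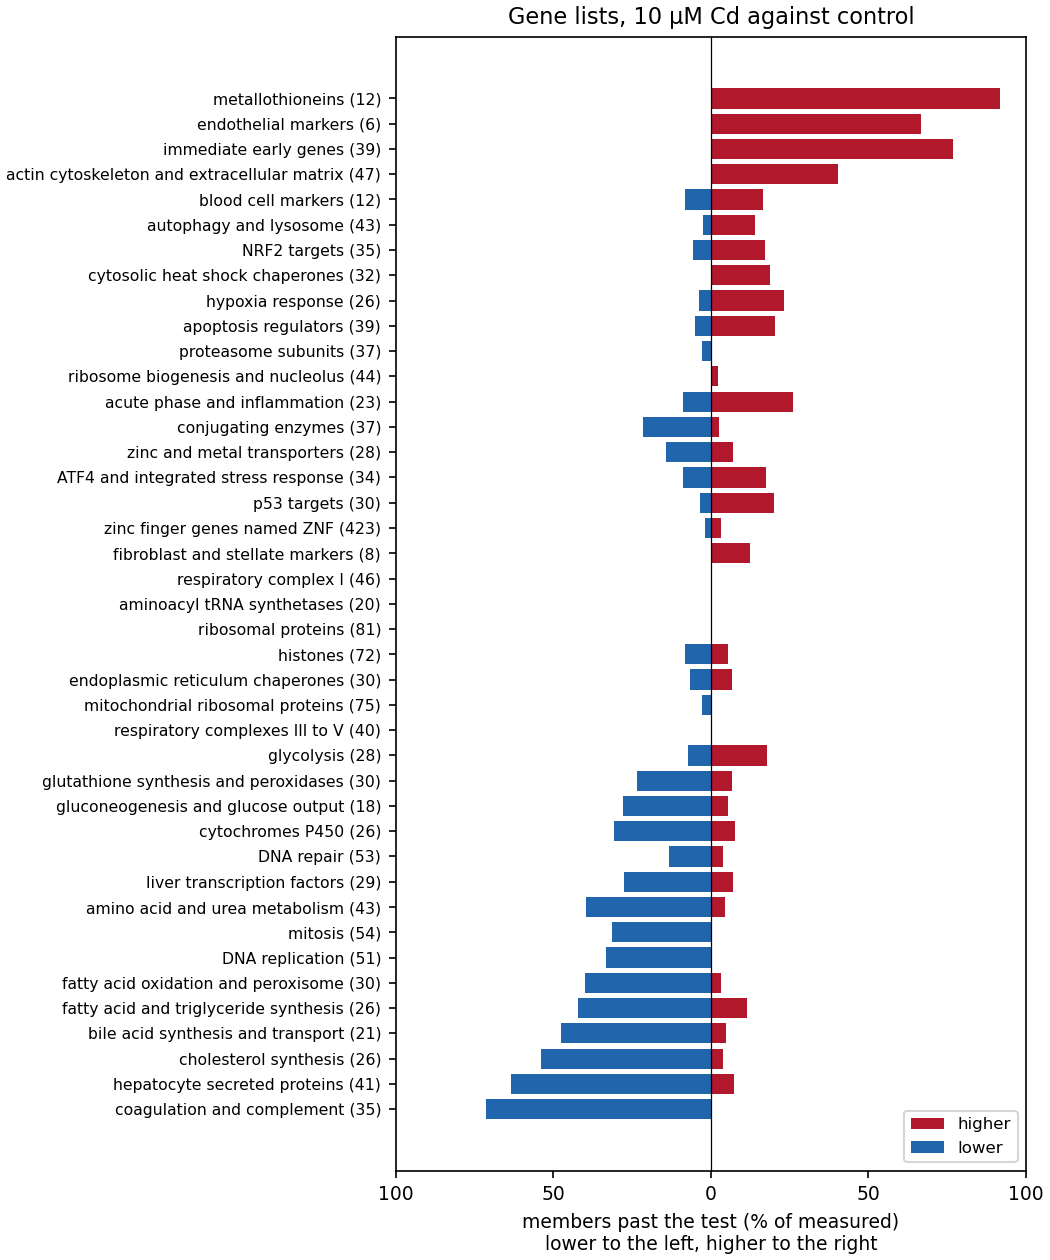
Share of the measured members of each of 41 gene lists that rose (red, to the right) or fell (blue, to the left) at 10 µM against control, in percent, with the number measured in brackets and lists ordered by median change. Metallothioneins (11 of 12 up) and immediate early genes (30 of 39 up) are at the top end, and coagulation and complement (25 of 35 down) at the bottom end.

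Lists of lipid, drug and amino acid metabolism had more members that fell than rose. Of 26 cholesterol synthesis genes 14 fell and 1 rose (19 and 1 adjusted over the list alone); MVK fell by 1.35 ± 0.20 (median -0.95, adjusted p = 0.19 with an estimated correlation). Of 26 genes of fatty acid and triglyceride synthesis 11 fell and 3 rose (14 and 4 adjusted over the list alone). Their median was -0.71 (adjusted p = 0.19 with an estimated correlation). MLXIPL, the carbohydrate response factor, fell by 2.03 ± 0.33 and PNPLA3 by 1.70 ± 0.26, whereas PLIN5 rose by 1.88 ± 0.37 and ACSL5 by 1.31 ± 0.16. Of 30 genes of fatty acid oxidation and the peroxisome 12 fell and 1 rose (20 and 1 adjusted over the list alone), with HADH at -1.70 ± 0.16 and EHHADH at -1.36 ± 0.15 (median -0.58, adjusted p = 0.0805 with an estimated correlation). Of 21 genes of bile acid synthesis and transport 10 fell and 1 rose (11 and 1 adjusted over the list alone), among them CYP8B1, of cholic acid synthesis (-2.67 ± 0.39), KLB (-2.75 ± 0.25) and ABCG8 (-1.72 ± 0.31), with a median of -0.89 (adjusted p = 0.0805 with an estimated correlation). Of 26 cytochromes P450 8 fell and 2 rose, with CYP19A1, the aromatase, at -2.13 ± 0.30 and CYP4F3 at -2.06 ± 0.18 (median -0.23, adjusted p = 0.0805 with an estimated correlation). Of 43 genes of amino acid and urea metabolism 17 fell and 2 rose (22 and 2 adjusted over the list alone), with GNMT, a glycine methyltransferase, at -2.80 ± 0.25 (median -0.55, adjusted p = 0.12 with an estimated correlation). Of 37 conjugating enzymes 8 fell and 1 rose (11 and 1 adjusted over the list alone); GSTA2 fell by 2.55 ± 0.36, GSTA1 by 2.52 ± 0.34 and SULT2A1 by 2.50 ± 0.18. Their median was 0.08 (-0.42 and 0.25 within slides 2 and 3) while their mean was -0.31 and camera's direction was down (adjusted p = 0.594 with an estimated correlation). Of 30 genes of glutathione synthesis and peroxidases 7 fell and 2 rose (8 and 2 adjusted over the list alone), with GPX2 at -1.24 ± 0.17 (adjusted p = 0.594 with an estimated correlation). Of 18 genes of gluconeogenesis and glucose output 5 fell and 1 rose (7 and 1 adjusted over the list alone), with PGM1 at -1.53 ± 0.21 and SLC37A4 at -1.40 ± 0.16 (adjusted p = 0.124 with an estimated correlation). With spike-in scaling the medians were -1.64 for cholesterol synthesis, -1.40 for fatty acid and triglyceride synthesis, -1.27 for fatty acid oxidation, -1.58 for bile acid genes, -0.92 for cytochromes P450, -1.24 for amino acid and urea metabolism and -0.61 for conjugating enzymes.

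In the lists of proliferation and repair, members past the test at 10 µM mostly fell, and most members did not pass over all genes. Of 54 mitosis genes 17 fell, none rose and 37 did not pass (25 fell adjusted over the list alone), with KIF15 at -1.16 ± 0.17, the phosphatase CDC25C at -1.14 ± 0.17 and CENPM at -1.01 ± 0.21. Their median was -0.56, and -0.69 and -0.35 within slides 2 and 3 (camera adjusted p = 5.52e-13, adjusted p = 0.0847 with an estimated correlation). Of 51 DNA replication genes 17 fell and 34 did not pass (34 fell adjusted over the list alone), with MCM2 of the replicative helicase at -1.24 ± 0.19 and ORC1 at -0.92 ± 0.16. Their median was -0.57, and -0.69 and -0.51 within slides 2 and 3 (camera adjusted p = 6.47e-13, adjusted p = 0.0805 with an estimated correlation). Of 53 DNA repair genes 7 fell and 2 rose (12 and 2 adjusted over the list alone), with the checkpoint kinase CHEK2 at -1.02 ± 0.17 and UNG at -0.85 ± 0.16 (median -0.27, adjusted p = 0.0805 with an estimated correlation). With spike-in scaling the medians of mitosis, DNA replication and DNA repair were -1.25, -1.26 and -0.955.

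Lists of other cell types and of basic machinery were read in the same way. Of 12 listed endothelial markers 6 were measured, and 4 of these rose at 10 µM, among them ESAM by 2.63 ± 0.38, TIE1 by 2.60 ± 0.30 and ROBO4 by 2.02 ± 0.23. Markers off in control and at 2 µM were kept only if above background at 10 µM, so this share and the median may run high. The list's median was 2.23, and 1.42 and 2.39 within slides 2 and 3 (camera adjusted p = 0.0131, adjusted p = 0.184 with an estimated correlation), and 1.54 with spike-in scaling. Of 12 blood cell markers 2 rose, CD3D by 2.16 ± 0.42 among them, and 1 fell (3 and 1 adjusted over the list alone), and of 8 fibroblast and stellate markers 1 rose. Camera shifted neither list, but fry called the blood cell markers (adjusted p = 0.0085, range over all alternatives 0.0085 to 0.944). Of 72 histone genes 4 rose and 6 fell, with H2AC1 at 2.09 ± 0.41 and H2BC5 at -1.25 ± 0.23. Of 423 zinc finger genes named ZNF 14 rose and 8 fell (6 and 1 adjusted over the list alone), with ZNF280A at 1.98 ± 0.30 and ZNF22 at -2.22 ± 0.40. No member of the ribosomal proteins (81 measured), respiratory complex I (46), respiratory complexes III to V (40) or aminoacyl tRNA synthetases (20) passed. Of 37 proteasome subunits 1 fell, PSMB9 (-0.86 ± 0.16), of 75 mitochondrial ribosomal proteins 2 fell and of 44 genes of ribosome biogenesis 1 rose, the last 3 genes not when adjusted over the list alone. Camera shifted none of these 7 lists here, but some alternatives did. The slide block shifted the mitochondrial ribosomal proteins (adjusted p = 0.0194, range over all alternatives 1.96e-05 to 0.938), and over all alternatives the adjusted p reached from 5.28e-10 to 0.954 for the ribosomal proteins, 2.54e-05 to 0.978 for complexes III to V, 0.00201 to 0.94 for complex I and 0.0333 to 0.928 for ribosome biogenesis. Medians within slides 2 and 3 had opposite signs for the ribosomal proteins (-0.37 and 0.60), complexes III to V (-0.41 and 0.40), complex I (-0.32 and 0.26), the mitochondrial ribosomal proteins (-0.38 and 0.26), the proteasome (-0.16 and 0.38) and the aminoacyl tRNA synthetases (0.09 and -0.31).

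In all, camera shifted 22 lists at 10 µM and an estimated correlation kept 2 of them. Fry, which does not compare a list with the other genes, ended 2 of the 22 calls and added 3. Of the 4 lists that the replicate block ended, namely the apoptosis regulators (0.144), conjugating enzymes (0.0772), gluconeogenesis (0.0772) and endothelial markers (0.0749), the slide block ended the first and last (0.164 and 0.062). Over all alternatives the adjusted p of these 4 lists reached from 0.0038 to 0.366, 0.00142 to 0.594, 0.00246 to 0.331 and 6.9e-05 to 0.184. All but the endothelial list, and the glutathione list too, also lost their call without some single array, the conjugating enzymes for instance without 10 µM replicate 1 (0.235) or control replicate 2 (0.168), gluconeogenesis without replicate 3 of 10 µM (0.159) or of control (0.0648), and the glutathione list without 10 µM replicate 1 (0.111) or 2 (0.0761) or control replicate 2 (0.0659) or 3 (0.122). The apoptosis regulators lost theirs in 8 of the 9 such fits.

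The count of genes moved with the model. The slide block gave 2435 up and 1826 down (2701 of the 2784 genes shared) and the replicate block 2896 up and 2245 down (2782 shared). Across genes, the fold changes within slides 2 and 3 correlated at r = 0.625, although genes are not independent replicates. Without control replicate 1 the counts were 893 up and 643 down, without 10 µM replicate 1 968 and 671, and without control replicate 3 731 genes were lower. Higher genes were 57.9% of the calls here, 46.5% with median scaling and 22.5% with spike-in scaling, where 201 genes rose and 692 fell. Of 149 named genes past the test at 10 µM, 122 kept their call whichever array was left out. With spike-in scaling 54 lost it, and 1 more, DNAJB11, changed sign.

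The third comparison set 10 µM against 2 µM and asked what differed between the doses. At 10 µM, 790 genes were higher and 531 lower than at 2 µM. Metallothioneins were not among them, while immediate early genes, chaperones and hepatocyte genes were. GADD45G was higher by 5.02 ± 0.57 (adjusted p = 0.00235), NPPC by 4.50 ± 0.48, ARC by 4.09 ± 0.56 and HSPA6 by 4.06 ± 0.40 (adjusted p = 0.00135), and TENT5C was at least 7.11-fold higher. C8B was lower by a log2 change of -3.02 ± 0.32 and ALDH8A1 by -2.87 ± 0.26, and PLIN1 was at least 4.66-fold lower and NOL4 at least 3.05-fold.

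None of the 12 metallothioneins passed between the doses in limma, with changes from -0.19 ± 0.20 for MT3 to 0.44 ± 0.45 for MT1H and a list median of 0.37, which was -0.25 with spike-in scaling. Of 39 immediate early genes 21 were higher at 10 µM (31 adjusted over the list alone) and none was lower, with GADD45B at 3.08 ± 0.26 and FOS at 2.48 ± 0.43 and EGR3 at least 2.99-fold higher. Their median was 1.23 (adjusted p = 0.0274 with an estimated correlation) and 0.61 with spike-in scaling. Among the heat shock chaperones 3 of 32 were higher, HSPA1A by 2.34 ± 0.30 (5 higher adjusted over the list alone; adjusted p = 0.15 with an estimated correlation), and among the genes of ATF4 and the integrated stress response 4 of 34, PPP1R15A by 2.16 ± 0.24 and ATF3 by 1.49 ± 0.19, with 3 lower (7 higher and 3 lower adjusted over the list alone). Of 47 actin and matrix genes 12 were higher (19 adjusted over the list alone), among them MMP3 by 2.42 ± 0.27 and PLAU, urokinase, by 2.25 ± 0.24. The list's median of 0.54 (adjusted p = 0.108 with an estimated correlation) was -0.08 with spike-in scaling.

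Of 35 coagulation and complement genes 16 were lower at 10 µM than at 2 µM and none higher (27 lower adjusted over the list alone). FGA differed by -2.62 ± 0.24, and the median was -0.99 (adjusted p = 0.0112 with an estimated correlation) and -1.61 with spike-in scaling. Of 41 hepatocyte secreted proteins 16 were lower and 3 higher (24 and 3 adjusted over the list alone), with ITIH1 at -2.17 ± 0.31, APOA5 at -1.99 ± 0.22 and HPX, hemopexin, at -1.76 ± 0.22 (median -0.82, adjusted p = 0.108 with an estimated correlation, and -1.44 with spike-in scaling). Of 43 genes of amino acid and urea metabolism 14 were lower (16, with 2 higher, adjusted over the list alone), ALDH6A1 by -1.62 ± 0.23, and of 29 liver transcription factors 4 were lower (9, with 1 higher, adjusted over the list alone), NR1H4 by -2.56 ± 0.26, CEBPA by -1.65 ± 0.20 and FOXA1 by -1.28 ± 0.15. For each of these lists the adjusted p was 0.108 with an estimated correlation. Of 54 mitosis genes 11 were lower (KIF15 at -1.04 ± 0.17) and of 51 DNA replication genes 14 (MCM2 at -1.21 ± 0.19), or 24 and 31 adjusted over the list alone, with medians of -0.55 each (-1.17 each with spike-in scaling) and an adjusted p of 0.0734 each with an estimated correlation.

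Camera shifted 18 lists between the doses, 2 of which held with an estimated correlation. Fry ended 3 of the 18 calls and added 4. The replicate block ended the calls of the conjugating enzymes (0.0573, range over all alternatives 0.000535 to 0.65) and gluconeogenesis (0.0683, range 0.00444 to 0.233). It also ended that of the endothelial markers (0.0834, range 0.000154 to 0.219). Calls were lost without 10 µM replicate 1 for the conjugating enzymes (0.309) and heat shock chaperones (0.075), without 10 µM replicate 2 for the endothelial markers (0.0628), without 10 µM replicate 3 for gluconeogenesis (0.169) and the aminoacyl tRNA synthetases (0.41), and without 2 µM replicate 2 for the conjugating enzymes (0.227), heat shock chaperones (0.0804) and gluconeogenesis (0.0569). The slide block gave 1613 genes higher and 991 lower (1276 of the 1321 shared), and the replicate block 2151 and 1422 (1320 shared). Without 2 µM replicate 1 or 3 or 10 µM replicate 1 the counts were 372 and 195, 270 and 172, and 315 and 190, and without replicate 2 of 2 µM or 10 µM 323 and 342 genes were lower. Higher genes were 59.8% of these calls, but 49.2% in the authors' deposited table, 47.6% with quantile normalization, 43.9% with median scaling and 30.4% with spike-in scaling.

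Both doses were then set side by side. The F test across the 3 groups called 1901 genes, 3046 with the slide block and 3989 with the replicate block. All 17 genes that rose at 2 µM also rose at 10 µM, where independent lists would share 1.36, and 16 of them stood higher at 10 µM than at 2 µM, although only 4 passed the test between the doses. No gene rose at one dose and fell at the other. Across genes the fold changes of the doses correlated at r = 0.627, beside a mean of 0.50 ± 0.008 (SD) in 100 simulations of unchanged groups against the same 3 controls. The simulated genes were independent and the arrays had no pairing by replicate number. That SD therefore does not measure the spread between arrays, and the mean ignores the pairing. With single arrays left out r ranged from 0.436 to 0.711, so whether it exceeds the no-change value stays open. The covariance was 0.133 beside 0.042, a difference of 0.091. Part of the overlap may come from the shared controls, which 3 arrays are too few to split. Without 2 µM replicate 2 the correlation was 0.436, below the simulated mean of 0.50. No simulation was run with that array left out, so 0.436 has no matching no-change value.

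**Figure D5:**
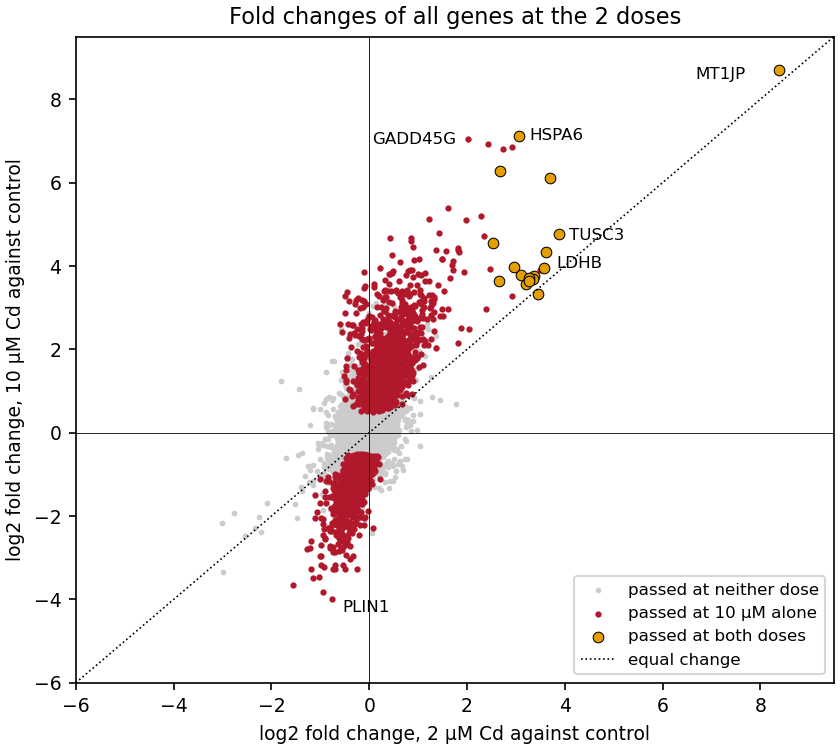
Log2 fold change against control of each of 20088 genes at 2 µM (x axis) and 10 µM (y axis), coloured by whether the gene passed at neither dose, at 10 µM alone or at both; the dotted line marks equal change. The 17 genes past the test at both doses lie in the upper right, and 16 of them lie above the line.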

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

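The tests of slide and scan date and of compressed signal in this part were chosen after their results were seen, whereas the counts of other splits were planned.

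The spike-in RNA, a signal outside the main measurement, lay further above the 75th percentile at 10 µM than in control, by 0.677 (log2), and was flagged for that difference between treated and control arrays. Its mean over 7 of 10 spike-in probes was 1.30 ± 0.31 (SD, n = 3) in control, 1.36 ± 0.34 (SD, n = 3) at 2 µM and 1.98 ± 0.77 (SD, n = 3) at 10 µM. The exact permutation p was 0.3, two-sided, and the smallest possible is 0.1. All 3 replicate pairs were higher at 10 µM, by 0.45, 0.37 and 1.22. The differences within a slide were 0.323 on slide 2 and 1.22 on slide 3, which neither slide nor scan date can produce, but each rests on 1 control array and has no spread of its own, so how much slide or scan date added stays open; a lower share of messenger RNA in the labelled RNA at 10 µM may also raise the spike-ins and was not tested.

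The metallothionein signal was 0.29 higher at 10 µM than at 2 µM, and a compressed signal of bright probes is one candidate explanation of so small a step. The brighter 9 metallothioneins, with changes from 0.34 to 0.44, could be limited in this way, since 0 of 241 other genes as bright passed with a rise of over 1, although 0 of them passed with a fall of over 1 either. The dimmer MT1F and MT1JP lay over 3 (log2) below the brightest gene and changed by 0.10 on average, and among 487 other genes in their range 0 passed with a rise of over 1 and 6 with a fall. With no comparison gene that passed with a rise of over 1, compressed signal could not be excluded for either part. A response that was already complete at 2 µM stays open as well, as untested.

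From 280 splits of the 9 arrays into groups of 3, 100 were drawn. Of these, 4 gave as many genes in the F test as the 3 doses did, the real one included. This share lies under 0.05 but does not exclude chance. The real count was 1901 and the highest of the others 2634. The other 3 splits as large were all the other drawn splits that kept the 10 µM arrays together, so they share the main structure of the samples. No split that parted these arrays gave more than 67 genes. The count thus reflects how far the 10 µM arrays lie from the rest, and it cannot separate control from 2 µM. Among 13 drawn splits with 1 array of each replicate number per group, as in the real one, the highest count was 5, and grouping by replicate number gave 170. For the contrasts there are only 10 splits of 6 arrays, too few for a share under 0.05; 1 of 10 gave as many genes each time, with 17 genes at 2 µM (highest other 1), 2784 at 10 µM (highest other 0) and 1321 between the doses (highest other 0).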

How the results depend on the processing

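Spike-in scaling, the first scan date only and the spots marked as outliers were alternatives chosen after the data were seen. Each group had 3 arrays, and 65.8% to 73.8% of spots on an array were well above background. Within 1.5 times the main value stayed the counts of genes higher at 2 µM in 14 of 28 alternatives, higher and lower at 10 µM in 20 and 18 of 28, higher and lower between the doses in 16 and 12 of 28, and in the F test in 16 of 26. The metallothionein signal against control moved by less than its spread in 26 of 26 alternatives at both doses. Of 12, 149 and 110 named genes past the test at 2 µM, 10 µM and between the doses, 1, 102 and 40 kept their call in every alternative except spike-in scaling, and 1, 75 and 21 in every one; of 17, 22 and 18 shifted lists 4, 2 and 2 kept theirs in every one, the others losing it mostly with an estimated correlation. The replicate block changed no list call beyond those given with the comparisons and, at 2 µM, respiratory complexes III to V (adjusted p = 0.0264, range over all alternatives 0.000706 to 0.933) and endothelial markers (0.0349, range 0.00777 to 0.586), which it added. For the values that follow, the cause was not tested except where fewer genes or arrays, or a stricter threshold, give it.

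Genes higher at 2 µM were 11 with median scaling, 5 with no filter, 11 with all 9 arrays above background, 7 with every probe, 8 with only the 2 groups, 4 at an adjusted p under 0.01 and 8 with outlier spots kept. Genes lower at 2 µM were 1 with array weights, 3 with the replicate block, 2 with the slide block and 1 with the scan date block. At 10 µM, higher and lower genes were 3116 and 2793 with array weights, 2896 and 2245 with the replicate block, 2435 and 1826 with the slide block, 727 and 501 at an adjusted p under 0.01, and 201 and 692 with spike-in scaling. Higher genes were 950 with normexp background, and lower genes 1881 with the scan date block and 620 with at least 2-fold. Between the doses they were 423 and 289 with normexp background, 2203 and 1673 with array weights, 2151 and 1422 with the replicate block, 1613 and 991 with the slide block, 1449 and 1089 with the scan date block, 229 and 141 at an adjusted p under 0.01, 62 and 142 with spike-in scaling, and 369 and 319 with the first scan date only. Higher genes were 525 in the authors' table, and lower genes 313 with no filter, 312 with only the 2 groups and 287 with at least 2-fold. The F test called 1199 genes with normexp background, 4413 with array weights, 3989 with the replicate block, 3046 with the slide block, 3088 with the scan date block, 801 at an adjusted p under 0.01 and 512 with spike-in scaling. The correlation between doses was 0.528 with no filter and 0.740 with the first scan date only. With spike-in scaling the metallothionein step between the doses was -0.328 and DNAJB11, an endoplasmic reticulum chaperone, turned from 0.55 to -0.136 at 10 µM. An estimated correlation left 4, 2 and 2 lists at 2 µM, 10 µM and between the doses, and fry called 4 at 2 µM.

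Leaving out each array in turn gave 4 to 18 genes higher and 0 to 0 lower at 2 µM, 893 to 1766 and 643 to 1608 at 10 µM, 270 to 763 and 172 to 649 between the doses, and 906 to 1954 in the F test. Shifted lists ranged over 10 to 22, 19 to 24 and 15 to 22, the correlation between doses over 0.436 to 0.711, and the metallothionein differences over 3.05 to 3.86, 3.31 to 4.15 and -0.04 to 0.48.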

Other observations

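Both tests in this part, of RNA from another cell line and of cancer testis genes, were planned before their results were seen, while the genes named here were chosen after their values were seen. Beyond the 17 called genes, the replicate block called 12 more at 2 µM, of which 9 were up and 3 down. Among them were the immediate early gene EGR1 (1.60 ± 0.36) and the phosphatase DUSP5 (1.41 ± 0.23), KRT37, a hair keratin (2.35 ± 0.41), MT1A, MT1M, MT2A, and PAIP2B, PAQR5 and TM4SF19, which were above background on no control array. The 3 lower genes were MRAP at -1.19 ± 0.18, PPP1R1A at -1.21 ± 0.63 and ZG16 at -1.56 ± 0.43, and all 3 fell at 10 µM without the block. The SEs given for these 12 genes come from the fit without the block, in which none of them passed at 2 µM. In limma with the block the adjusted p was 0.0378 for MRAP, 0.0355 for PPP1R1A and 0.0212 for ZG16. Albumin (ALB), the main secreted protein of hepatocytes, stood at -0.47 ± 0.22 at 10 µM and did not pass, while transferrin (TF) fell by 0.78 ± 0.22 and the apolipoproteins APOA1 and APOB by 1.37 ± 0.17 and 0.82 ± 0.22.

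At 2 µM, 56 genes were well above background on all 3 arrays but on no control array, and 0 the other way round. At 10 µM these were 219 and 20, and 29 genes were on at both doses. The 75th percentile of the signal at 2 µM was 1451, 1432 and 864 in replicates 1 to 3, beside 923, 1091 and 779 in their paired controls, and whether array brightness bears on these counts was not tested. At 2 µM no list showed a shift beyond the 17 already described, by camera, among them mitosis, DNA replication, the p53 targets and the ATF4 genes.

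Genes above background on no control array and on all arrays at both doses included TUSC3, LDHB, LOC100129788 and CT45A1, at least 7.87-fold, 3.09-fold, 1.71-fold and 1.28-fold higher at 2 µM. RNA of another cell line mixed in would bring that line's abundant transcripts. The 9 markers of other lines that were dim in the controls had a median change of 0.393 at 2 µM, from -0.459 to 0.753. This argues against a large share of RNA from a line rich in these markers at 2 µM, if less firmly for CT45A1 and LOC100129788 with their low bounds. It cannot speak on a small share or on a line that lacks these markers. LDHB and TUSC3 were themselves dim at 2 µM, with normalized log2 signals of -3.90 and -3.11 in replicate 1. A small share could therefore be enough for them, and RNA of another line stays open at 2 µM. None of 19 measured markers passed, but only 17 of 20088 genes passed at this dose, so that count adds little. At 10 µM the median of the dim markers was 1.82, and 6 of the 9 rose, namely ANXA1 (at least 3.57-fold, as no control array was well above background), EMP1 (2.65 ± 0.40), AXL (2.56 ± 0.26), CAV2, KRT17 and FOSL1, while CAV1 (0.58 ± 0.41), for instance, did not pass. Genes of hepatocytes fell at this dose, such as 25 of 35 coagulation and complement genes, and 4 of 6 measured endothelial markers rose. Markers of either kind that were off in the controls could be kept through the 10 µM arrays alone, so the shares that rose may run high. RNA of other cells and a change in the cells themselves both stay open at 10 µM. Of the other 10 markers, which the controls also expressed, 6 rose, and the brightest at 10 µM were LGALS1 (1.68 ± 0.41), S100A6 (1.97 ± 0.49) and CAVIN1 (1.44 ± 0.33), which rose, and TGFBI (-0.38 ± 0.16), which did not pass. A loss of silencing across cancer testis genes could bring up CT45A1. The CT45 and SPANX genes were left out of its test, though CT45A1, SPANXA1 and others of them did turn on. Of the other 38 such genes that were off in all controls, 2 (5.26%) turned on at 10 µM, beside 213 of 8753 other genes off there (2.43%). The Fisher exact p was 0.238, two-sided, which leaves this open.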
